A study of Mus musculus with 2 samples.

How the data were processed

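Chromatin from mouse hindbrain at embryonic day 11.5 was immunoprecipitated for H3K4me3, histone H3 trimethylated at lysine 4, a modification found at the promoters of active and poised genes, and the recovered DNA was sequenced. Per the labels, there was 1 group of 2 biological replicates of the B6NCrl strain, each a pool of dissected hindbrains of both sexes: replicate 1 came from 109 embryos and replicate 2 from 88. No treatment, mutant or second tissue enters the comparisons, so the design allows replicate against replicate and, within the tissue, gene group against gene group.

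The authors deposited 4 peak lists on the mm10 build. Per the file headers, the list of each replicate was derived from the alignments of that replicate and 2 further files not used here, the pooled list from the alignments of both replicates and the same further files, and the replicated list from the pooled list and both single lists. Every replicated peak was found to be a row of the pooled list. The peak caller, its version, its threshold and the rule by which a peak counted as replicated are not given in the sources used here. Each row holds a start and end, a display score between 10 and 1000 that the authors deposited and that was not used here, a signal value, a −log10 p, a −log10 q and a summit offset in bp, which was not used here. The signal value is the enrichment at the peak as the authors deposited it, a ratio with values above 1, in the narrowPeak format named per the file headers; what it is relative to is not given in the sources used here. The −log10 p and −log10 q values are those the authors deposited; the lowest −log10 p in the 4 lists was 2.05 and the lowest −log10 q was 0.157, so each list reaches down to peaks with a false discovery rate above 0.05. Signal values were used to describe, rank and filter peaks within a list and to set the 2 replicates' ranks side by side. Read counts and alignments were not used here, so the sequencing depth of each library is unknown and no value could be given a counting error from reads.

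Gene models came from GENCODE release M21 on GRCm38, whose chromosome lengths hold every peak of the lists. A gene was called marked when a peak overlapped the 1000 bp on either side of any annotated transcription start site (TSS) of that gene. A domain was a run of peaks that overlapped or lay within 1000 bp of each other, and the width of a gene was that of its widest domain reaching a TSS window; genes that share a domain share its width. There were 21938 protein-coding genes. For each gene, the CpG ratio (observed over expected CpG) and GC content of the 2 kb round the 5′ end were taken from the GRCm38 sequence. Coordinates are given on mm10, counted from 1.

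Gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. Peaks on unplaced or unlocalized scaffolds were left out of the gene comparisons, since the gene models used cover chromosomes 1 to 19, X and Y. The 25 lists cover Hox genes in 3 sets, regional and neuronal regulators, progenitor and neuronal genes, and proliferation, housekeeping and ribosomal protein genes. Others hold markers of further cell types that the dissection could hold or should lack. Of the lists, 2 were chosen by symbol pattern, those of ribosomal protein and chemoreceptor genes. The symbols Drgx and Ahsp were not found in the annotation. Each list's marked share in the replicated list was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted by the Benjamini-Hochberg method over 25 lists. Median domain widths of lists with at least 10 marked members were compared with the other marked genes by two-sided permutation tests with 100000 resamples, adjusted over 16 lists. Pairs of lists were compared by Fisher's exact test and by permutation of domain width with unmarked genes at 0, and X-linked with autosomal genes by Fisher's exact test. These tests run across genes, which are not independent replicates, since neighbours in a cluster share domains, and their p-values say nothing about variation between embryos. Values of the 2 replicates are given as mean ± SD with n = 2; shares carry 95% Wilson intervals, which cover counting error over genes or peaks only.

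Overlap between peak lists means at least 1 bp. Chance overlap came from 20 seeded random placements of the other list's peaks on the same chromosomes. Agreement of signal was computed across peaks matched 1 to 1 as each other's largest overlap. The named genes were the 12 with the widest domains among those marked in both replicates, the 8 with the highest signal, up to 4 marked and 4 unmarked members of each list, and up to 10 list members marked in 1 replicate only; the non-coding genes were chosen later, without seeing their values, and other genes are named as chosen after their values were seen. In the matched comparisons, each member was replaced 100000 times by a gene of the same CpG and GC bin. The bins describe the 5′ end alone, whereas a mark at any TSS counts, and the number of TSSs per gene was not matched. Alternatives covered the overlap rule, a −log10 q of at least 5, the 20000 strongest peaks, TSS windows of 500 and 2500 bp, 5′ ends only, merging within 3000 bp or not at all, the pooled list, each replicate alone, a background without chemoreceptor genes and a background matched on CpG ratio (10 bins) and GC content (5 bins within each). Counting each domain once and the matched and family-filtered X comparisons were added after the data had been seen.

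Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and merging code was tested on the peak lists against bedtools 2.31.1 and gave equal counts in 25 of 25 comparisons. The list test was tested on simulated data over 21938 genes with a base marked share of 65%: of 100 planted lists of 20 genes at 95%, 75 were called, of 100 at 25%, 94 were called, and of 500 unchanged lists, 4 were called. The width test called 25 of 25 lists planted 3-fold wider and 1 of 111 unchanged lists. Simulated marks and widths were drawn independently for each gene, without the dependence on CpG content or the shared domains of the real data. These rates therefore do not carry over to the real gene lists, and planted widths below 3-fold were not tried.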

Results

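H3K4me3 was profiled in mouse hindbrain at embryonic day 11.5, when rhombomere-derived progenitors are dividing and neurons of the brainstem and cerebellar anlage are being born. The data are 2 biological replicates of 1 group, pools of 109 and 88 embryos of both sexes, each with its own peak list, plus a pooled and a replicated list of the authors. Replicate 1 had 26012 peaks covering 31.7 Mb and replicate 2 had 27580 peaks covering 30.0 Mb; their median widths were 990 and 812 bp. The pooled list held 24565 peaks and the replicated list 20999. Because no read counts were used, the depth behind each list is unknown, and the number of peaks is not a measure of it.

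The first question the design allows is how far the replicates share their peaks. Of the peaks of replicate 1, 81.5% (Wilson interval 81.1 to 82.0%) were overlapped by a peak of replicate 2, and of those of replicate 2, 82.4% (82.0 to 82.8%) were overlapped by one of replicate 1. Randomly placed peaks gave 2.54% ± 0.104 and 2.45% ± 0.0769 (mean ± SD over 20 placements). Sharing followed strength: in both replicates every peak in the upper 5 of 10 equal groups by signal value was shared, whereas 31.9% of the weakest group was shared in replicate 1 and 39.4% in replicate 2. Unshared peaks were short and weak, with median widths of 237 bp in replicate 1 and 217 bp in replicate 2 against 1279 and 1092 bp for shared peaks, and 34.4% and 28.8% of them lay at a TSS against 78.0% and 76.3%. Across 19911 peaks matched 1 to 1, Pearson's r of log2 signal was 0.968 and Spearman's rho of signal 0.965; peaks are not independent replicates, so no p is given. Of the 24565 pooled peaks, 3566 were absent from the replicated list, and their median width was 232 bp. Among replicated peaks, 19801 overlapped a peak in both replicates and 1198 lacked an overlap in at least 1 of them.

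H3K4me3 lay mainly at promoters. In the replicated list 77.1% of peaks (Wilson interval 76.5 to 77.7%) overlapped a window round the TSS of any annotated gene, against 9.97% of randomly placed peaks. By class, 72.2% touched a protein-coding TSS window (6.31% ± 0.199 at random), 4.94% only that of another gene type (3.71% ± 0.135), 11.2% lay elsewhere in a protein-coding gene (34.8% ± 0.327) and 11.6% lay outside (55.2% ± 0.348). Within the replicate lists the first class was smaller, at 64.1% ± 1.18 (SD, n = 2). Peaks at coding TSSs had a median signal value of 31.1 and a median width of 1645 bp, and peaks elsewhere in coding genes 4.50 and 485 bp. The share at any TSS depends on the annotation and the list: it was 66.5% with 5′ ends only and 67.9 to 69.9% in the replicates' own lists.

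Of 21938 protein-coding genes, 14231 (64.9%, Wilson interval 64.2 to 65.5%) were marked, and the replicates gave 65.2% ± 0.184 (SD, n = 2). Both replicates marked 14167 genes, 98.1% of those marked in either. Promoter CpG content separated marked from unmarked genes: 6.65% of the 4388 genes with the lowest CpG ratios were marked, against 99.3% of the 4388 with the highest. The widest domains lay in the Hox clusters and at Nr2f2 and Pou3f3. A domain of 56691 bp on chromosome 11 (96298763 to 96355453) covered Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6, and measured 57354 ± 142 bp in the replicates (SD, n = 2). Hoxa1 and Hoxa2, with the overlapping gene 5730596B20Rik, shared 25840 bp on chromosome 6 (52156556 to 52182395), and Hoxd3 and Hoxd4, with the overlapping model Gm28230, shared 19027 bp on chromosome 2 (74722168 to 74741194). Nr2f2, an orphan nuclear receptor of neural and vascular development, had 23132 bp (replicates 22398 ± 3724, SD, n = 2), and Pou3f3, a POU factor of neural progenitors, 22136 bp (26076 ± 6358, SD, n = 2). Median width over all marked genes was 1921 bp, and 58 genes reached 10 kb.

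The 8 genes with the highest signal values were other than the 12 named for the widest domains, and Hoxd4, which ties with the last of those, was left out of the 12 by alphabetical order. Hnrnpu, which encodes a nuclear RNA-binding scaffold protein, had 83.1, Msl1, of a histone acetyltransferase complex, 82.2, and Arid1a, a chromatin remodelling subunit, 80.0. Mex3c, an RNA-binding ubiquitin ligase, and Pgs1, an enzyme of cardiolipin synthesis, both had 79.9, followed by the splicing factor Sfpq (79.7), cytoplasmic actin Actg1 (77.6) and the PHD finger gene Phf13 (77.2). Their domains were 1845 to 8507 bp wide, the widest at Arid1a, with 8936 bp in replicate 1 and 5157 bp in replicate 2. Over marked genes, the rank correlation of width and signal was 0.487.

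Anterior Hox genes, which pattern the rhombomeres, were marked throughout, and fewer posterior ones were. All 15 genes of paralogue groups 1 to 5 carried a replicated peak, against 7 of 16 of groups 9 to 13 (two-sided Fisher's exact test, p = 0.000816). Mean domain width, unmarked genes at 0, was 23384 bp (SD 22326 over genes) against 448 bp (SD 631), a difference of 22936 bp (permutation test, p = 1e-05, the smallest the permutations can give). Groups 6 to 8 lay between: 8 of 8 were marked, with 56691 bp at Hoxb6, 10513 bp at Hoxa6 and 5626 bp at Hoxb7 and Hoxb8, but their median signal was 9.60 against 25.6 in groups 1 to 5. Hoxa6 was decided by 1 library, with 14045 bp in replicate 1 and 1086 bp in replicate 2. Among posterior genes, Hoxb9 had 1829 bp, Hoxa13 1359 bp, Hoxd9 1339 bp and Hoxd11 1076 bp, at signal values of 5.62, 5.82, 9.11 and 4.11; Hoxd9 and Hoxd11 were wider in replicate 2 (2042 and 1059 bp) than in replicate 1 (1082 and 659 bp). Hoxa9, Hoxa10, Hoxa11 and Hoxc9 had no replicated peak; Hoxa11 had 204 bp in replicate 1 alone and Hoxd10 281 bp in replicate 2 alone. The share of posterior genes marked was also below the 97.6% of genes with like CpG and GC content (adjusted p = 0.000125 by resampling), though not below all other genes (adjusted p = 0.148, Fisher's exact test) except at −log10 q of at least 5 (4 of 16 marked) and in the 20000 strongest peaks (6 of 16). Against all other genes the anterior list was marked more often (adjusted p = 0.00359, Fisher's exact test), though not on the matched background, and groups 6 to 8 did not pass (adjusted p = 0.0793, Fisher's exact test) except with 5′ ends only. Replicate 1's list marked 10 posterior genes and replicate 2's marked 8, so the count moves with weak peaks. The width difference was 13134 bp with each domain counted once, a comparison added after the data had been seen, and 8134 bp without merging. Anterior domains were not all wide: in the replicated list those of Hoxa3, Hoxb1 and Hoxd1 were narrower than that of the posterior gene Hoxb9. Hoxa3 had 1956 bp in replicate 1 and, joined to the domain of Hoxa1, 29828 bp in replicate 2. Hoxa3, Hoxb1 and Hoxd1 were named after their values were seen.

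**Figure D1:**
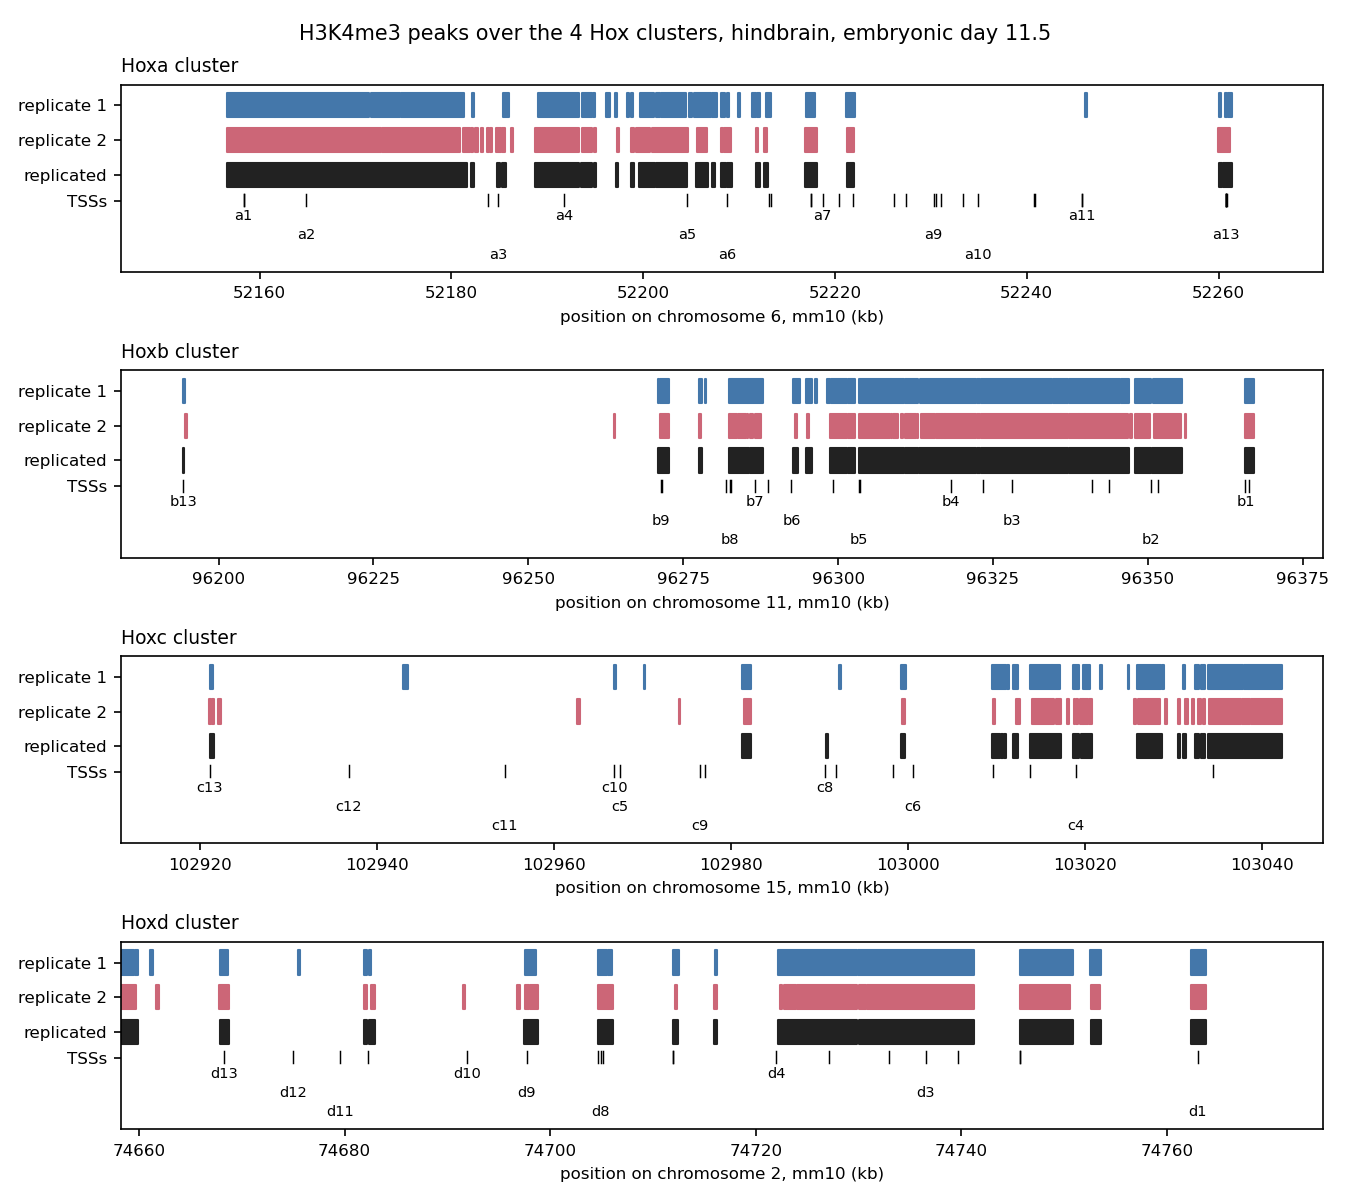
Position of H3K4me3 peaks (bars) over the 4 Hox clusters in replicate 1, replicate 2 and the replicated list; the horizontal axis is the mm10 position in kb and ticks are annotated TSSs, with each gene's label at its median TSS. Bars run together over most anterior genes, as in the 56691 bp domain over Hoxb2 to Hoxb6, though Hoxb1 and Hoxd1 each have a short separate bar. Over the posterior genes bars are short or missing.

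Regulators of the hindbrain itself had domains several times wider than regulators of the forebrain. Each of 22 hindbrain segmentation and rhombic lip genes was marked, with a mean width of 7292 bp (SD 4390 over genes), against 1611 bp (SD 1827) for 21 forebrain transcription factors, a difference of 5681 bp (permutation test, p = 1e-05, the smallest the permutations can give). Widest were the TALE homeobox genes Meis2 (18018 bp) and Meis1 (14175 bp), cofactors of Hox proteins, and the neighbouring zinc finger genes Zic1 and Zic4 (12080 bp), which act in cerebellar development. Their replicate values were 17977 ± 156, 14328 ± 230 and 12023 ± 81.3 bp (SD, n = 2). Of the forebrain factors 16 of 21 were marked: Lhx2, a selector gene of the cortex and eye field, had 7651 bp, the interneuron genes Dlx2 4241 bp and Lhx8 2561 bp, and the telencephalic regulator Foxg1 2929 bp. Their median signal was 10.2 against 28.5 for the hindbrain genes. Six3, Nkx2-1, Arx and Tbr1 had no replicated peak in their TSS windows, though windows of 2500 bp reached one for Six3 and Arx. Each of these genes had a short peak in 1 replicate: 342 bp at Six3 in replicate 2, and 227, 238 and 291 bp at Nkx2-1, Arx and Tbr1 in replicate 1. Neurod6, named after its values were seen, had no peak in either. The difference in marked share was 23.8 points (two-sided Fisher's exact test, p = 0.0211), but with replicate 1's list alone it was 9.52 points (p = 0.233, Fisher's exact test), so only the width difference held in both. Against all other genes the hindbrain list was marked more often (adjusted p = 0.000348, Fisher's exact test), though not on the matched background, and the forebrain list did not pass (adjusted p = 0.394, Fisher's exact test) except in replicate 1's and the pooled list. Midbrain and isthmic organizer genes, which flank the hindbrain, were marked in 17 of 18 cases, with 10273 bp at Lmx1b, 10165 bp at En1, 7946 bp at Gbx2 and 6638 bp at Pax2; Fgf17 was the exception, with 274 bp in replicate 2 alone. Their share passed the test (adjusted p = 0.00972, Fisher's exact test) except with 5′ ends only and on the matched background, and their median width was 5083 bp (adjusted p = 4e-05, permutation test), an excess over other marked genes that fell to 1435 bp without merging.

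Genes of neural tube patterning and neurogenesis were marked almost without exception and over wide domains. Every one of 18 neural progenitor genes was marked (adjusted p = 0.00143 by Fisher's exact test), with a median width of 6919 bp against 1921 bp for other marked genes (permutation test, adjusted p = 4e-05, set by the smallest p the permutations can give). Widest were Pou3f2 (15691 bp), Pax6 (15534 bp), the zinc finger gene Zic2 (11212 bp) and the stem cell factor Sox2 (11075 bp). Sox2 measured 18686 bp in replicate 1 and 10869 bp in replicate 2. Of 19 dorsoventral progenitor genes 18 were marked, among them Pax3 (17058 bp), a dorsal gene, Irx3 (9760 bp) and the ventral gene Nkx6-1 (9395 bp), with a median width of 4900 bp. Dbx2, of the intermediate neural tube, was unmarked in both replicates, though windows of 2500 bp reached a replicated peak for it. All 19 neuron subtype regulators were marked, with a median width of 4604 bp: Lhx5 had 16582 bp, Gata3 14270 bp, Lhx1 11478 bp and Gata2 9880 bp, genes of interneuron classes. Gata3 was narrower in replicate 2, at 6482 bp against 15215 bp. The 22 early pan-neuronal genes were all marked (adjusted p = 0.000348, Fisher's exact test), against 69.6% expected from their CpG content, with a median of 3635 bp; Ina and Nefm, neurofilament genes, had 6745 and 6014 bp, neuronal tubulin Tubb3 6472 bp and the helix-loop-helix gene Nhlh1 5790 bp. Each of these lists passed the permutation test of width at adjusted p = 4e-05, and Fisher's exact test of share, at adjusted p = 0.00972 for dorsoventral and 0.000880 for neuron subtype genes. Without merging they still passed the width test, but their medians exceeded that of other marked genes by less: 3170 bp for progenitor, 1208 bp for dorsoventral, 739 bp for neuron subtype (adjusted p = 0.00960, permutation test) and 1287.5 bp for pan-neuronal genes. With resampling matched on CpG and GC content in place of the exact test, the pan-neuronal and neuron subtype lists were still higher (adjusted p = 0.000125 and 0.0466) and the progenitor and dorsoventral lists were not. That match covers the 5′ end only, so a difference in the number of TSSs per gene could add to the excess.

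Among transmitter genes, the inhibitory genes Slc32a1 (10181 bp), which loads GABA and glycine into vesicles, Slc6a5 (8594 bp), the glycine transporter of glycinergic neurons, and Gad1 (8394 bp), which makes GABA, had wide domains, as did the glutamate transporter Slc17a6 (6471 bp). With 5′ ends only, Gad1 was unmarked. In both replicates Th, Dbh, Ddc and Tph2, enzymes of catecholamine and serotonin synthesis, had no peak. The monoamine transporter genes Slc6a2, Slc6a3, Slc6a4 and Slc18a2 were marked, at 1162, 943, 1715 and 1164 bp, as was the cholinergic pair Chat and Slc18a3, which share 2608 bp; these 6 were named after their values were seen. The list as a whole, 13 of 17 marked, did not differ from other genes in share (adjusted p = 0.466, Fisher's exact test) or width (adjusted p = 0.0672, permutation test), but the width result depends on the setting: the list was wider in both replicates' own lists (adjusted p = 0.0394 for replicate 1 and 0.00270 for replicate 2, permutation tests), in the pooled list, with merging within 3000 bp and without merging (adjusted p = 0.0241). Astrocyte and myelin genes, 11 of 20 marked, also did not differ (adjusted p = 0.394 for share, Fisher's exact test, and 0.337 for width, permutation test): Slc1a2 had 3788 bp, Gja1 3179 bp, Sox10 2940 bp and Slc1a3 1964 bp, while the astrocyte genes Gfap, Aqp4, S100b and Aldoc had no peak in either replicate. Without merging, this list was narrower than other marked genes (adjusted p = 0.0457, permutation test). Of roof plate and choroid plexus genes 16 of 20 were marked. Msx1 (7056 bp, with 7760 bp in replicate 1 and 4501 bp in replicate 2), Bmp4 (5460 bp), Wnt1 (4084 bp) and Bmp7 (3508 bp) were the widest. Ttr, Folr1, Aqp1 and Kcne2 were unmarked, while the choroid epithelium genes Kl (1285 bp) and Clic6 (1164 bp), named after their values were seen, were marked. The list passed neither test (adjusted p = 0.286 for share, Fisher's exact test, and 0.101 for width, permutation test), but was wider in replicate 1's and the pooled list and with merging within 3000 bp.

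**Figure D2:**
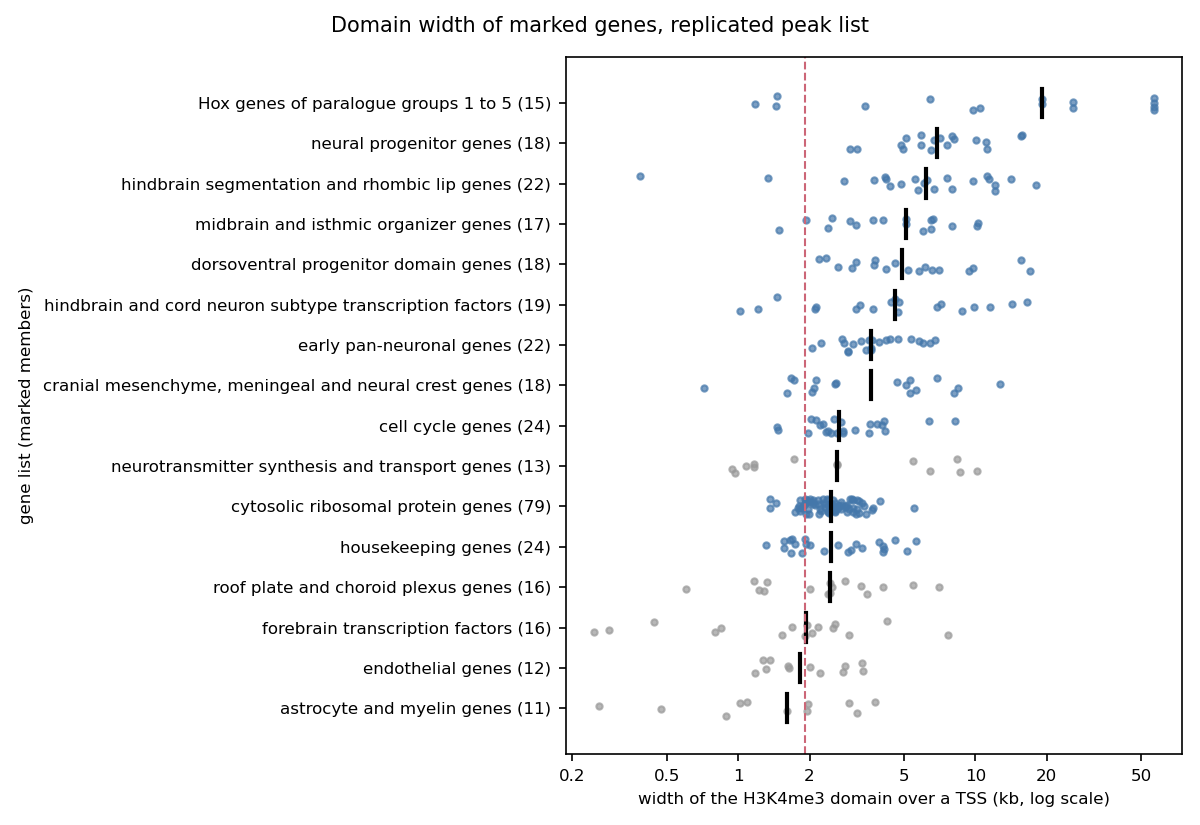
Width of the H3K4me3 domain over a TSS in kb (log scale) for each marked member (points) of the 16 lists tested, with the list median (black bar) and the median of all marked genes, 1921 bp (dashed line). Blue lists passed the permutation test and grey ones did not; the anterior Hox genes have the highest median, 19027 bp.

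Genes used by dividing or by all cells were marked almost without exception. All 24 cell cycle genes and all 24 housekeeping genes were marked (adjusted p = 0.000156 for each, Fisher's exact test), as were 79 of 82 cytosolic ribosomal protein genes (adjusted p = 9.71e-11); the unmarked Rpl10l, Rpl39l and Rpl3l are paralogues of restricted expression. With resampling matched on CpG and GC content in place of the exact test none of these 3 lists passed (adjusted p = 1, 0.223 and 0.483), the expected shares being 97.1%, 91.4% and 93.5%. The lists' median widths were 2669, 2458 and 2469 bp (adjusted p = 0.00637, 0.0465 and 0.000249, permutation tests), and their median signal values 36.9, 42.0 and 51.5. The width tests were not matched on CpG content. Among the 4388 genes with the highest CpG ratios, marked ones had a median width of 2477 bp, so these widths may not be particular to the lists. The D cyclins Ccnd2 and Ccnd1 stood above the rest of the cell cycle list, at 8196 and 6395 bp, ahead of Rrm2 (4162 bp) and Pcna (4138 bp), which serve DNA synthesis. Among housekeeping genes Chmp2a, Polr2a, Tubb5 and Tbp had 5638, 5132, 4597 and 4122 bp, and among ribosomal protein genes Rpl18, Rpl7, Rps9 and Rps15a had 5523, 3980, 3686 and 3680 bp. Rpl18 measured 5098 bp in replicate 1 and 2477 bp in replicate 2, and Rps15a 2623 and 4372 bp. Housekeeping genes did not pass the width test in replicate 2's list, without merging or at −log10 q of at least 5.

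Hepatocyte, germ cell, epidermal, microglial and immune, erythroid and muscle genes were marked less often than other genes. None of 20 hepatocyte genes was marked in the replicated list or in either replicate (Wilson upper limit 16.1%; adjusted p = 6.72e-09, Fisher's exact test), including Alb, Afp, Apoa1 and Apoa2; windows of 2500 bp reached peaks for Apoa1 and Apoa2. Of germ cell genes 2 of 20 were marked, Tex14 (1347 bp) and Dazl (760 bp), with Ddx4, Mael, Sycp1 and Sycp3 unmarked. Epidermal genes gave 3 of 19, namely Lor, Krt10 and Krt1, with Krt5, Krt6a, Krt14 and Krt15 unmarked. Lor was marked by replicate 1 alone of the single lists and lost its mark with windows of 500 bp. Krt10 and Krt1 lost theirs with 5′ ends only. Microglial and immune genes gave 4 of 20: Irf8 (1314 bp), Tmem119 (1170 bp), Fcgr3 (361 bp) and Cd68 (341 bp), with Ptprc, Csf1r, Cx3cr1 and Aif1 unmarked. Erythroid genes gave 5 of 18, among them Tal1 (4620 bp), Klf1 (1869 bp), Epor (1841 bp) and Nfe2 (1310 bp), while the globin genes Hba-a1, Hba-a2, Hba-x and Hbb-bh1 had no peak. Muscle genes gave 7 of 20, led by Mylpf (3587 bp), Myl3 (3078 bp), Ckm (1045 bp) and Myod1 (753 bp), with Myh6, Myh7, Tnnt2 and Tnnt3 unmarked. Several of these widths moved with the library: in replicates 1 and 2 Ckm had 1844 and 785 bp, Myod1 469 and 1769 bp, Tmem119 1021 and 1572 bp and Fcgr3 1167 and 337 bp. Adjusted p was 3.47e-06 for germ cell, 7.78e-05 for epidermal, 0.000163 for immune, 0.00359 for erythroid and 0.0122 for muscle genes (Fisher's exact tests). With resampling matched on CpG and GC content in place of the exact test, the hepatocyte (adjusted p = 0.0153) and germ cell lists (adjusted p = 0.000125) stayed lower and the other 4 did not pass.

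Olfactory and vomeronasal receptor genes were almost free of the mark: 3 of 1418 carried a replicated peak (0.212%, Wilson interval 0.0720 to 0.620%), against 69.3% of other genes. The 3 were Vmn1r4 (2953 bp in replicate 1 and 1727 bp in replicate 2), Olfr94 and Olfr658, and Olfr1, Olfr10, Olfr1000 and Olfr1002 were unmarked. Markers of endothelium and of mesenchyme and crest did not differ from other genes in share. Of endothelial genes 12 of 20 were marked (adjusted p = 0.645, Fisher's exact test), with 3360 bp at the VEGF receptor gene Kdr, 3324 bp at Egfl7, 2813 bp at Mfsd2a and 2756 bp at Flt1, and no peak at Pecam1, Cdh5, Tek or Tie1. Egfl7 was narrower in both single lists, at 2021 bp in replicate 1 and 985 bp in replicate 2, and Kdr had 3420 and 1859 bp. Cranial mesenchyme and neural crest genes were marked in 18 of 23 cases (adjusted p = 0.248, Fisher's exact test) and were wider than other marked genes, with a median of 3634 bp (adjusted p = 4e-05, permutation test); in replicate 2's list they did not pass, with a median of 2478 bp, and without merging the excess was 585 bp (adjusted p = 0.0369, permutation test). Tfap2a had 12667 bp, Pdgfra 8482 bp, Tfap2b 8124 bp and Foxc1 6921 bp, and Tcf21, Meox1, Lum and Dcn were unmarked. In all, 10 of the 25 lists were marked more often than other genes and 7 less often; matched on CpG and GC content these numbers were 2 and 4. In the width tests on the replicated list, which were not matched on CpG content, 11 of 16 lists were wider and none narrower. Without merging 1 list was narrower (astrocyte and myelin genes), as was 1 in the pooled list and in replicate 1's list (posterior Hox genes, which reach 10 marked members there).

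**Figure D3:**
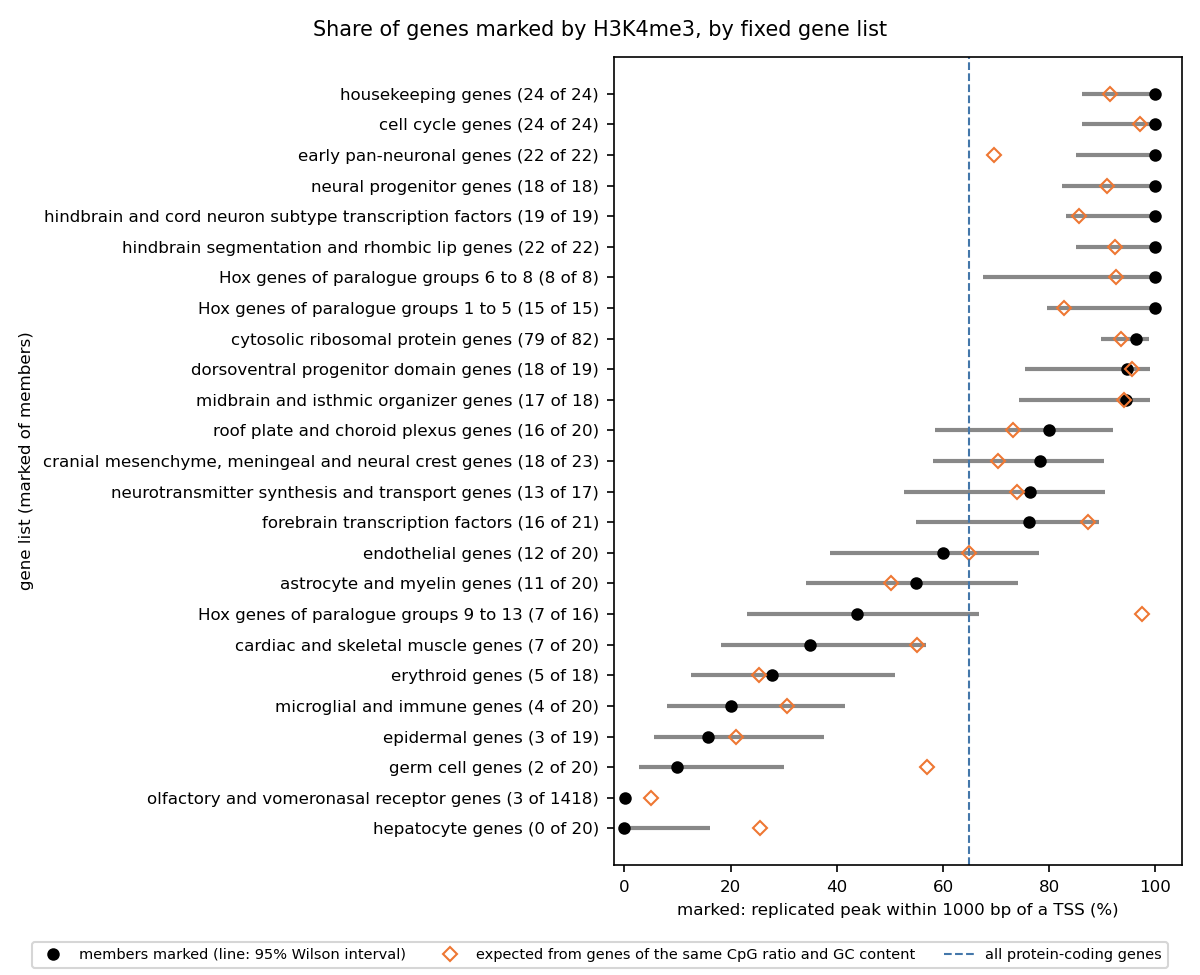
Share of each gene list marked by H3K4me3 in the replicated list, in percent (black points, with 95% Wilson intervals), beside the share expected from genes of the same CpG ratio and GC content (open diamonds) and the share of all protein-coding genes, 64.9% (dashed line). Neural progenitor, pan-neuronal, neuron subtype, hindbrain, cell cycle, housekeeping and Hox group 1 to 8 lists lie at 100%, hepatocyte and receptor genes near 0, and posterior Hox genes and germ cell genes lie far below their expected shares.

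List members marked in 1 replicate and not in the other numbered 20 of 1935, 13 in replicate 1 and 7 in replicate 2. Widest was Lor, with 2241 bp in replicate 1, followed by Cd68 with 677 bp and Six3 with 342 bp in replicate 2. Lor's peak in replicate 1 had a signal value of 35.4, and every peak of that strength was overlapped by a peak of replicate 2. A peak of replicate 2 thus lay at Lor but did not reach its TSS window, and with windows of 500 bp Lor was unmarked. Olfr1033 (307 bp), Tbr1 (291 bp) and Olfr658 (278 bp) were marked in replicate 1, and Hoxd10 (281 bp), Fgf17 (274 bp), Nkx2-5 (244 bp) and Aldh1l1 (243 bp) in replicate 2.

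Both pools held male and female embryos, and genes of the X chromosome were marked less often than those of the autosomes. Of 948 X-linked protein-coding genes 481 were marked (50.7%, Wilson interval 47.6 to 53.9%), against 13746 of 20807 autosomal genes (66.1%, 65.4 to 66.7%), a difference of -15.3 points (two-sided Fisher's exact test, p = 2.97e-21). The replicates gave -15.5 and -15.3 points. Without chemoreceptor genes, which lie almost wholly on autosomes, it was -19.7 points. Fewer X-linked genes had CpG-rich promoters, with 20.9% of them in the upper 2 of 5 groups by CpG ratio against 41.2% of autosomal genes. Against autosomal genes of like CpG and GC content the difference was -3.40 points (p = 0.00178 by resampling in place of the exact test, a comparison added after the data had been seen).

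**Figure D4:**
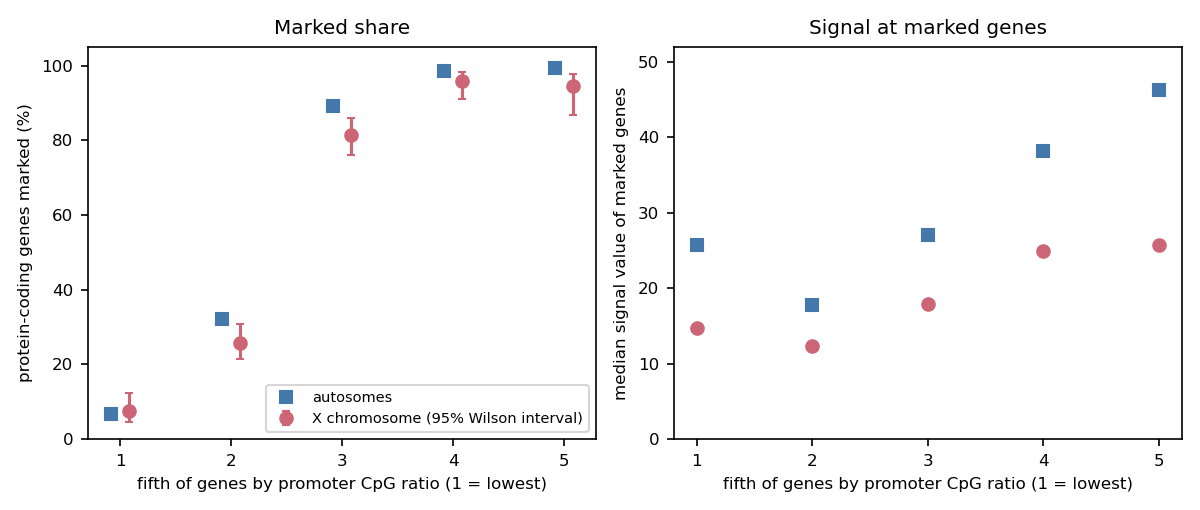
Share of protein-coding genes marked, in percent (left), and median signal value of the marked genes (right), for autosomal genes (squares) and X-linked genes (circles, with 95% Wilson intervals of the share) in 5 groups by promoter CpG ratio, 1 the lowest. X-linked genes lie below autosomal ones in marked share in groups 2 to 5, with 81.4% against 89.1% in group 3, and in median signal in all 5.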

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

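With 1 group of 2 samples there was no test for outlying samples and no contrast between groups, so only data outside the comparisons of the report were looked at here. The test of genes that define other tissues, the X comparisons matched on CpG and GC content or without like-named copies, and the tests of signal on the X chromosome were chosen only after the results had been seen.

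A signal was present on sequences the gene comparisons do not reach: 12 replicated peaks lay on 6 unplaced or unlocalized scaffolds, with a median signal value of 5.37 and a range from 2.35 to 33.7, and 0 of them at an annotated TSS. Replicate 1 had 10 such peaks and replicate 2 had 18. A further signal lay in pooled peaks left out of the replicated list: 110 protein-coding genes were marked by such peaks alone, with a median signal of 3.11 and a median width of 243 bp. They include 8 members of the fixed lists other than receptors, namely Hoxa9, Hoxa10, Hoxd10, Six3, Arx, Tbr1, Fgf17 and Slc4a1, the last chosen after its values were seen.

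The lower marked share of X-linked genes was weighed against 3 technical explanations. Promoter CpG content could account for most of the gap, since the difference of -15.3 points became -3.40 points against autosomal genes in the same CpG and GC bins. The expected share of 54.1% lies just above the X interval of 47.6 to 53.9%. Whether the remaining difference goes beyond CpG content cannot be told, as the bins describe the 5′ end alone and the number of TSSs was not matched. Whether 1 active X per cell leaves X marks under the caller's threshold cannot be told: in the upper 2 of 5 groups by CpG ratio the difference was -3.54 points, but that test cannot decide, as 0.731% of the autosomal marks there would fall under a signal of 3.09, the median of pooled peaks left out of the replicated list, at 50% of their own, and in groups 2 and 3, where signal is weaker, it was -6.41 and -7.68 points. The clusters of like-named copies that could be found, 143 X-linked and 3609 autosomal genes, did not make the gap, which was -19.4 points without them. Copies were matched by the letters that open the symbol, so families whose symbols begin with a digit stayed in and were not tested. At 50% of their signal, 17.2% of the autosomal marks in group 2 and 5.10% in group 3 would fall under 3.09. A weaker X signal may thus make up part of the gap in those groups, but little of it in the upper 2. Marked X genes in the upper 2 groups had a median signal of 25.2 against 42.1 for autosomal genes, a ratio of 0.599 (permutation test, p = 2e-05, the smallest the permutations can give). No biological explanation was tested.

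The few marks at genes of other tissues and at receptor genes, 24 in 7 lists, were weighed against 3 explanations. Peaks reaching from the promoter of a neighbouring protein-coding gene explain at most a part. Of the 24, 20.8% (interval 9.24 to 40.5%) shared a peak with another protein-coding gene, close to the 21.7% of all marked genes. Those 5 were Mylpf with Tbc1d10b, Myl3 with Pth1r, Ckm with Klc3, Tex14 with Rad51c and Vmn1r4 with Nt5c3. Non-coding neighbours were not examined. CpG content may set which members are marked, as marked members had a mean CpG ratio 0.338 above unmarked ones (0.459 against 0.121, permutation test, p = 1e-05, the smallest the permutations can give), and 0.243 above without receptor genes. The ratio was taken round the 5′ end, whereas Krt1, Krt10, Nfe2, Nkx2-5 and Olfr94 lost their mark with 5′ ends only. For these genes the ratio does not describe the marked site. Cells of those tissues in the dissection stay open: 0 of 13 genes that define liver, blood, muscle or epidermis, the globins among them, were marked in either replicate, but genes with so few CpGs are seldom marked (19.1% of the lower 2 of 5 groups), and how many cells a peak needs is unknown.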

How the results depend on the processing

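The Hox, hindbrain against forebrain and X chromosome comparisons kept their direction under each alternative run, the shares of 4 lists and the widths of 4 lists, the latter in 11 values, changed sign under some alternative, and sizes moved as follows; the cause was not tested except where the construction gives it. Peak overlap (replicate 1, then replicate 2) was 76.1% and 78.3% with 50% of a peak covered, 70.0% and 66.0% with 50% of both, 90.6% and 97.7% at −log10 q of at least 5 and 89.9% and 93.6% among the 20000 strongest peaks. Pearson's r was 0.972 on −log10 p, 0.957 at −log10 q of at least 5 and 0.967 with reciprocal matches. The promoter share was 74.1% and 83.9% with windows of 500 and 2500 bp, 82.4% at −log10 q of at least 5, 79.05% in the 20000 strongest peaks, 71.1% in the pooled list, 66.5% with 5′ ends only and 67.9 to 69.9% without either replicate; the share of genes marked was, in the same order, 64.5%, 65.8%, 64.2%, 64.6%, 65.4%, 61.2% and 65.1 to 65.3%. Lists differing in share numbered 16 to 18 except on the CpG and GC matched background, where 6 passed, 5 of them among the 17 of the report; lists differing in width numbered 10 to 14. The hindbrain against forebrain difference in marked share was no longer past the threshold with windows of 500 bp (19.3 points) or 2500 bp (14.3 points) or the pooled list (9.52 points), and ranged from 9.52 to 19.05 points without either replicate. Differences of lists that had not passed, or lost their call on the matched background, changed sign there for forebrain (-11.1 points), dorsoventral (-0.855), astrocyte and myelin (4.79) and erythroid genes (2.34). Width differences of lists that had not passed changed sign for forebrain factors (-440 bp unmerged, -181 at −log10 q of at least 5, -94 in the strongest peaks, -380 to -169 without either replicate), endothelial genes (118 merged within 3000 bp, 142 in the pooled list, 92 to 101.5 without either replicate), roof plate genes (-342 unmerged) and astrocyte and myelin genes (-241 to 19.5 without either replicate). Among the comparisons of the report 56 of 88 alternative values stayed the same, 4 lost their call and 28 moved further. Staying the same meant keeping the call or moving by less than the spread or interval. For the numbers of lists that passed, it meant staying within a set fold of the main number, a looser rule. Of list shares 228 of 249 kept their direction and call, 11 kept the direction and lost the call, 6 gained a call and 4 changed sign, dorsoventral and erythroid genes losing their call with it; of list widths these numbers were 103 of 127, 4, 9 and 11. Named genes kept their width within the spread in 1397 of 1710 cases. Unmarked genes that stayed unmarked counted as kept, which raises that number. With 5′ ends only, 9 of 171 named genes lost their mark: Hoxd11, Gad1, Egfl7, Nfe2, Krt10, Krt1, Olfr94, Nkx2-5 and Aldh1l1. Windows of 500 bp lost Cd68 and Lor, and windows of 2500 bp gained Six3, Arx, Dbx2, Apoa1 and Apoa2. No paired analysis was possible because there is 1 group and no groups are compared. Counting each domain once and the matched and like-named X comparisons were chosen after seeing the data. Depth is unknown, so what it limits could not be measured.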

Other observations

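The tests of neuron subtype regulators against neural progenitor and pan-neuronal genes were chosen only after the result had been seen. The comparison matched on width and CpG content was chosen before its own result, but for a list whose low signal had already been seen in these data. The non-coding genes were chosen after the data had been seen, but without their values.

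Several non-coding genes of neural development were marked, some of them within the domain of a coding neighbour, and so were non-coding genes of general or other function. Hotairm1 lay within the 25840 bp domain of Hoxa1, and Hottip, at the posterior end of that cluster, was unmarked in both replicates. Pantr1, next to Pou3f3, shared its 22136 bp domain, Lhx1os the 11478 bp domain of Lhx1, and Sox2ot the 11075 bp domain of Sox2. Rmst, a regulator of neurogenesis, had 5174 bp, Miat 4676 bp and the imprinted gene Meg3 2892 bp, while the forebrain transcripts Six3os1 (274 bp) and Dlx6os1 (1691 bp, in the domain of Dlx6) had less and Otx2os1 had no replicated peak. Malat1, a nuclear RNA of most cells, had 8242 bp, the snoRNA host genes Gas5 and Snhg1 had 4264 and 3550 bp, each shared with a coding neighbour, and the imprinted gene H19 1861 bp. The nuclear RNA Neat1 had 1357 bp, with 1385 bp in replicate 1 and 2695 bp in replicate 2. Away from coding TSSs, 7.38% of 5367 lincRNA genes were marked (Wilson interval 6.71 to 8.11%), against 0.934% of 9635 processed pseudogenes (0.761 to 1.15%).

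Sex-linked genes carried the mark in these pools of both sexes. Of 183 protein-coding genes on the Y chromosome 4 were marked, Kdm5d (999 bp), Eif2s3y (1576 bp), Uty (953 bp) and Ddx3y (1078 bp), single-copy genes expressed in many tissues. Xist, the RNA that coats the inactive X, had 2491 bp, with 2652 ± 214 bp in the replicates (SD, n = 2), and its antisense partner Tsix 806 bp.

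Neuron subtype regulators combined wide domains with low signal. Their 19 marked members had a median signal of 11.5 (quartiles 7.06 and 16.8) at a median width of 4604 bp. The combination is not particular to this list. Median signal was 18.6 at 5083 bp for midbrain and isthmic, 20.2 at 4900 bp for dorsoventral and 16.1 at 3634 bp for mesenchyme and crest genes, against 35.9 for other marked genes. Of the wider lists, only progenitor, cell cycle, housekeeping and ribosomal protein genes exceeded other marked genes in median signal. Width or CpG content did not account for the low signal of neuron subtype regulators, as marked genes matched on both had a median signal of 39.0 (95% of 10000 draws between 29.0 and 47.9). The match used groups by width, the widest without an upper limit, so it was coarse for the widest members. A candidate explanation is that each regulator is active in a small part of the cells, so that bulk tissue dilutes its mark: mean signal was 13.3 (SD 7.34 over genes), a difference of -30.1 from neural progenitor genes (43.4, SD 12.03; permutation test, p = 1e-05, the smallest the permutations can give) and of -15.4 from pan-neuronal genes (28.7, SD 12.8; p = 7e-05, permutation test). This ordering was seen before it was tested, and the dorsoventral, midbrain and mesenchyme lists were not tested against the neuron subtype list. The share of cells was not measured, so a lower level of the mark in every cell stays open.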
